A study of Eohaustorius estuarius with 16 samples.

How the data were processed

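Gene expression was measured with custom one-colour Agilent arrays, labelled with the dye Cy3, for 8 RNA extracts of cyfluthrin-exposed amphipods and 8 of solvent controls, 1 array per extract. The arrays lay on 4 slides of 4. Slides 1 and 2 held exposed extracts 1 to 4 and 5 to 8, and slides 3 and 4 held control extracts 1 to 4 and 5 to 8. Total RNA was purified on columns, per the labels' protocols. The treatment was taken from the labels. No pair among the 120 pairs of arrays had identical signals.

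The deposited scanner files give, per the file headers, intensity values from Agilent Feature Extraction version 10.7.3.1, while the submitters' processing notes name version 9.1. The processed signal is an intensity on a linear scale from which the software had subtracted background, and it is not scaled between arrays, per the file headers. The spot and local background medians deposited beside it are intensities with no correction. Further deposited columns, other than intensities, are flags of 0 or 1 for spots well above background, outliers and saturation, per the file headers; no non-control spot was saturated on any array. The authors' value table holds log2 values. How it was made is not given in the sources used here, so it was set against the scanner files. After quantile normalization of the log2 processed signals and centring of each probe on its median over the 16 arrays, the slope of the authors' values on these was 0.988 to 1.00 per array (r from 0.9998 to 1.0000). Scale, centring and direction are thereby known. The medians of the table's columns were -0.011, -0.0018, -0.011, 0.00032, 0.037, 0.0015, 0.11 and -0.0065 for exposed extracts 1 to 8. They were -0.054, -0.0099, -0.029, 0.038, 0.016, -0.0031, 0 and 0.0009 for control extracts 1 to 8.

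Control spots and spots with an outlier flag were left out. The log2 processed signal of each spot was reduced by the array's 75th percentile over non-control spots, and the spots of a probe (3 for 14357 probes, 2 for 366) were averaged. Signal relative to this percentile is called scaled signal. A probe counted as well above background on an array when more than a share of 0.5 of its unflagged spots were. Probes were tested when this held on at least 6 of the 8 arrays of at least 1 group, which left 9765 probes (66.3%) on 5955 contigs. Exposed and control arrays were compared with limma 3.58.1 (lmFit, eBayes) in R 4.3.3, without covariates, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Tests of single measures per array were two-sided exact permutation tests. Tables were handled with data.table (version 1.17.8) and jsonlite 2.0.0, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

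The fit was tested on simulated data with 200 changed probes among 9765. With 8 arrays against 8 it recovered 8.96% of 1.5-fold, 46.3% of 2-fold and 83.3% of 4-fold changes, and 0 of its 92 calls were false. With 6 against 8 arrays, the 2 dim arrays left out, it recovered 35.8%, 76.1% and 92.4%, and 6.85% of its calls were false. The simulated noise was normal and independent between probes and arrays, without slide or scan day effects and without a background floor. These rates therefore do not give the share of false calls in the real data.

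The rule for named probes, fixed before the data were examined, would have taken annotated probes. The files pair probes only with contig numbers, so the part of the rule that needs no annotation was used: the 2 largest rises and the 2 largest falls past the threshold with the same sign in all 4 pairings of an exposed with a control slide. For the same reason the gene lists that had been fixed, among them ion channels, detoxification enzymes, cuticle and markers of tissues, were not tested.

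Alternatives for the main comparison were quantile, median and spike-in scaling (6 of 10 spike-in probes were above background on all arrays and were used), normexp background correction with an offset of 50, the authors' value table, other filters on dim probes, flagged spots kept, slide as a random block or slide means, array position or replicate number as a block, a trended and robust variance, array weights, other thresholds, and leaving out arrays or slides. Normexp was run on the spot medians, since the files used here hold no spot means. Fits without cyfluthrin 7 and 8, alone or with other changes, and a fit with 1 probe per contig were added after seeing the data.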

Results

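The samples were total RNA of whole bodies of Eohaustorius estuarius, a burrowing estuarine amphipod that is widely used in sediment toxicity tests. Animals had lived for 10 days in sediment spiked with cyfluthrin, a pyrethroid insecticide, at a nominal 1.6 µg/kg, or in sediment that had received only the solvent. Pyrethroids act on the voltage-gated sodium channels of nerve cells. There were 8 extracts from exposed animals and 8 from solvent controls, all prepared in 1 laboratory, and each was hybridised to 1 one-colour array in laboratory C. The series belongs to a study of how comparable microarray data are between laboratories, and the arrays of laboratory C were analysed here. The labels call the samples extracts and replicates, so p-values measure the spread between these extracts. The labels speak of 8 exposed and 8 control amphipods, as many as there are extracts. Whether an extract came from 1 animal or several is not stated beyond that.

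Each array held 43803 spots outside the control spots, for 14723 probes drawn from 8610 assembled contigs. The files pair probes only with contig numbers and not with gene names, so probes are given by their IDs. On 14 arrays the 75th percentile of the processed signal lay between 190.5 (cyfluthrin 1) and 396.9 (control 5) scanner units. Cyfluthrin 7 reached 21.3 and cyfluthrin 8 reached 6.65, and these are called the 2 dim arrays. Spots well above background made up 34.3% of cyfluthrin 7 and 14.6% of cyfluthrin 8. In the other exposed arrays the share ran from 69.5% to 76.9%, and in the controls from 42.7% (control 1) to 71.0%. Over all 16 arrays the mean share was 61.6% ± 23.6 (SD, n = 8) in the exposed group and 62.7% ± 9.56 (SD, n = 8) in the controls (two-sided exact permutation test, p = 0.913). Without the 2 dim arrays the exposed mean was 73.9% ± 2.79 (SD, n = 6) against the same control mean (two-sided exact permutation test, p = 0.0073, 0.059 after Benjamini-Hochberg adjustment over 8 such tests). The 2 arrays left out had the lowest shares of the exposed group, so leaving them out raised its mean, and this p-value does not allow for that choice. The number of arrays limits the precision of all values.

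**Figure D1:**
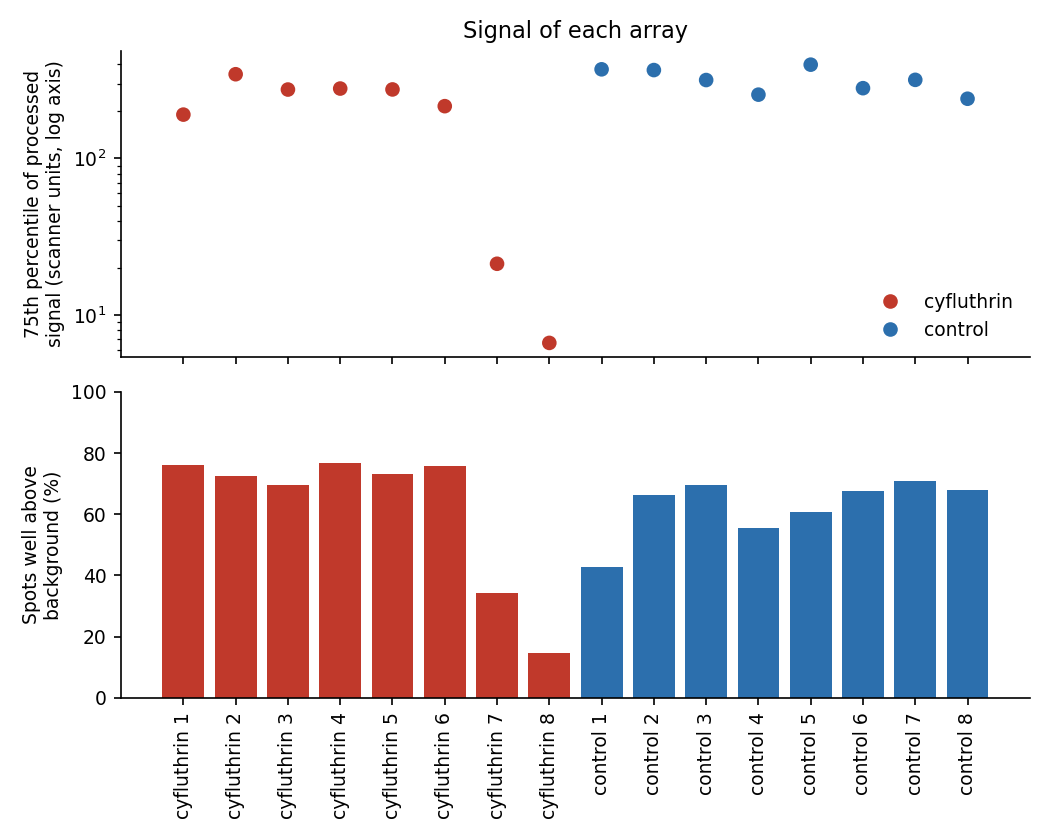
Signal of the 16 arrays, with cyfluthrin-exposed extracts in red and solvent controls in blue. The upper panel gives each array's 75th percentile of processed signal in scanner units on a log axis, and the lower panel the percent of non-control spots well above background; cyfluthrin 7 and 8 stand at 21.3 and 6.65 units while the other arrays lie between 190.5 and 396.9.

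The main comparison asked which transcripts differed between exposed and control animals after 10 days. Of 9765 probes tested, 2493 (25.5%) passed the threshold, 1584 of them higher and 909 lower in the exposed animals (limma, Benjamini-Hochberg adjusted p under 0.05). They lay on 1755 contigs, of which 1175 had a higher probe and 580 a lower one. Among the higher probes the median log2 fold change was 1.04, and among the lower probes it was -0.76. Changes of at least 2-fold were seen for 854 higher and 202 lower probes, and 97 probes rose by at least 4-fold while 9 fell by as much. Without the 2 dim arrays, a setting chosen after seeing the data, 3892 probes passed (2512 higher, 1380 lower). Of the 2493 probes, 2337 were among them. Under several alternatives fixed before the data were seen far fewer of the 2493 were called: 1186 of them with quantile normalization (1445 calls in all), 1161 with spike-in scaling (2468), 1119 with the authors' deposited values (1324), 849 with normexp background correction (1111), 375 without control slide 3 (377), 223 without control slide 4 (223) and 169 with slide means, 2 against 2 (174).

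The balance of rises and falls depended on how the arrays were scaled. With each array's 75th percentile 63.5% of the calls were higher, against 44.1% with the median, 37.9% with quantile normalization, 36.7% in the authors' value table and 10.2% with the spike-in controls. These scalings moved the median log2 fold change of all tested probes from 0.16 to -0.07, -0.08, -0.08 and -0.49, in that order, so directions are relative to the scaling. They also depended on the 2 dim arrays. Without these, a setting chosen after seeing the data, quantile normalization gave 51.0% of calls higher and a median of 0.07. The 75th percentile then gave 64.5% higher. Spike-in scaling was not run without the 2 dim arrays. The slope fitted to the spike-ins, per the file headers, was 0 on cyfluthrin 8 and 0.81 to 0.90 on the other arrays. Cyfluthrin 8 entered the spike-in scaling, so the 10.2% and the median of -0.49 are less certain. The balance also differed with signal level. With the tested probes in 4 bands of about equal size by signal, 921 were higher and 8 lower in the lowest band, and 101 were higher and 290 lower in the highest band. Without the 2 dim arrays these counts were 888 and 192 in the lowest band and 563 and 338 in the highest. The lowest processed signal was 2.29 units on cyfluthrin 7 and 1.95 on cyfluthrin 8, against 75th percentiles of 21.3 and 6.65. Scaled signals of dim probes were thus held up on these arrays, which raises their fold change. The lowest band had a median scaled signal of -3.36 on the other 14 arrays. Its median log2 fold change was 0.71 with the 2 dim arrays and 0.38 without them. Of the higher probes, 75 were not well above background on any control array.

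The rises at the top of the range formed a set of their own. Rises of at least 8-fold were found for 57 probes on 32 contigs, with a median log2 fold change of 3.71 (13.0-fold) and an SD over probes of 0.33. Only 4 probes passed the threshold with a log2 fold change from 2.5 to 3, and 36 did from 2 to 2.5, so that the 57 probes were parted from the bulk of the rises. With the 75th percentile scaling and all 16 arrays no tested probe fell by as much as 8-fold, but the probes of contig 3 did under spike-in scaling. The log2 fold changes of the 57 probes lay between 3.05 and 4.78. Of the 27 contigs with a pair of probes on the array, 25 had both in the set. In the controls 23 of the 57 probes were well above background on all 8 arrays and 5 on none, so the fold changes of the other probes rest on control signal that was not above background on every array. Relative to each probe's mean over the exposed arrays, the median of the set ran from -0.55 to 0.53 in the exposed arrays and from -4.80 (control 8) to -2.33 (control 3) in the controls. All 57 probes also passed the threshold, higher, under median, quantile and spike-in scaling and without the 2 dim arrays. The 8-fold limit itself depended on the processing: 54 of the 57 reached it with median, 52 with quantile and 32 with spike-in scaling. After normexp background correction all 57 passed, with a median log2 fold change of 2.18, but 0 reached 8-fold. With normexp and without the 2 dim arrays the median was 2.52, and 19 reached 8-fold. This set was chosen after its values were seen.

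**Figure D2:**
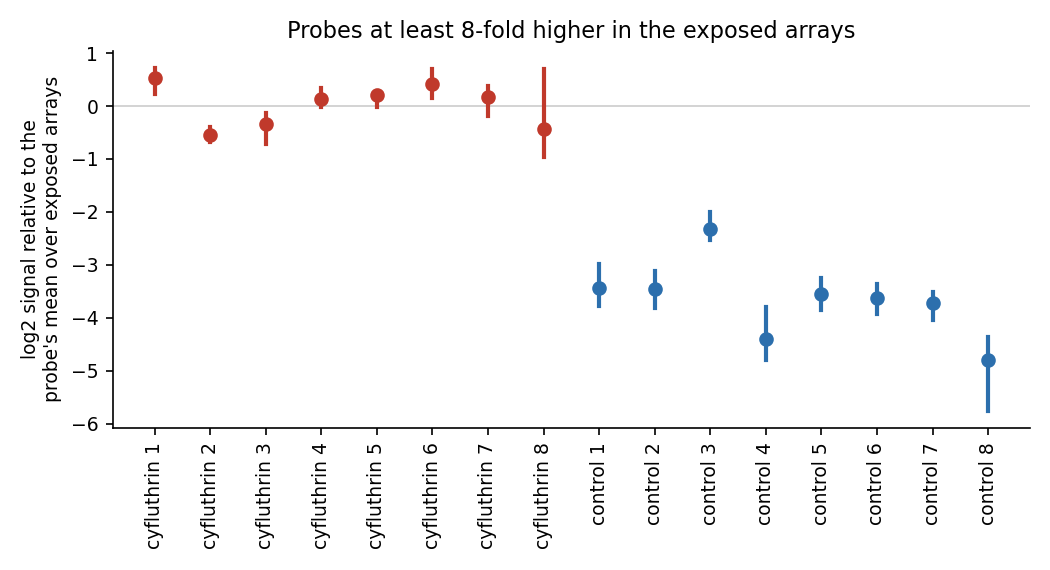
Signal of the 57 probes that were at least 8-fold higher in the exposed animals, on the log2 scale relative to each probe's mean over the exposed arrays (red, exposed; blue, control). Points are medians over the probes and bars run from the lower to the upper quartile; medians lie from -0.55 to 0.53 in the exposed arrays and from -4.80 to -2.33 in the controls.

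With the 75th percentile scaling, the largest rise was that of contig 5795, whose probes both belong to this set. Its probe CUST_2449_PI425439380 had a log2 scaled signal of 0.64 ± 0.61 (SD, n = 8) in exposed and -4.14 ± 0.79 (SD, n = 8) in control extracts, a log2 fold change of 4.78 (SE 0.33, limma adjusted p = 1.87e-07). It was well above background on 7 exposed and 4 control arrays. The other probe of the contig, CUST_2450_PI425439380, gave 1.80 ± 0.55 (SD, n = 8) against -2.64 ± 0.86 (SD, n = 8), a log2 fold change of 4.44 (SE 0.34, limma adjusted p = 1.87e-07). For both probes the lowest exposed array lay above the highest control array. The size of the rise depended on the processing, since the normexp setting gave log2 fold changes of 2.52 for CUST_2449_PI425439380 and 2.76 for CUST_2450_PI425439380. That setting also used spot medians and an added offset of 50, and adding a constant to 2 signals lowers the ratio between them. How much of the lowering came from each change was not tested. Without the 2 dim arrays, a setting chosen after seeing the data, normexp gave 2.65 for CUST_2449_PI425439380 and 3.14 for CUST_2450_PI425439380.

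The largest fall was that of contig 3. Probe CUST_1780_PI425439775 had a log2 scaled signal of 0.06 ± 1.93 (SD, n = 8) in exposed and 2.83 ± 2.24 (SD, n = 8) in control extracts, a log2 fold change of -2.77 (SE 0.93, limma adjusted p = 0.0377). Probe CUST_1779_PI425439775 of the same contig fell by 2.75 on the log2 scale (SE 0.91, limma adjusted p = 0.0355). The groups overlapped: CUST_1780_PI425439775 stood at 3.86 in cyfluthrin 3 and at -1.74 in control 8. The calls for the contig depended on single arrays. Without any one of cyfluthrin 1, 4, 6 or 7 or control 1, 2, 3, 4 or 5 neither probe passed the threshold, and without cyfluthrin 2 CUST_1780_PI425439775 did not, with log2 fold changes from -2.80 to -2.36 in those fits. The size of the fall was also unsteady. For CUST_1780_PI425439775 and CUST_1779_PI425439775 the log2 fold change was -3.42 and -3.40 under spike-in scaling, -3.42 for both without control 8 and -3.75 and -3.82 without control slide 4. Without control slide 3 it was -1.79 and -1.68 (limma adjusted p = 0.386 and 0.401). Both probes also belong to a group of 36 probes whose signal varied widely within each group of extracts.

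**Figure D3:**
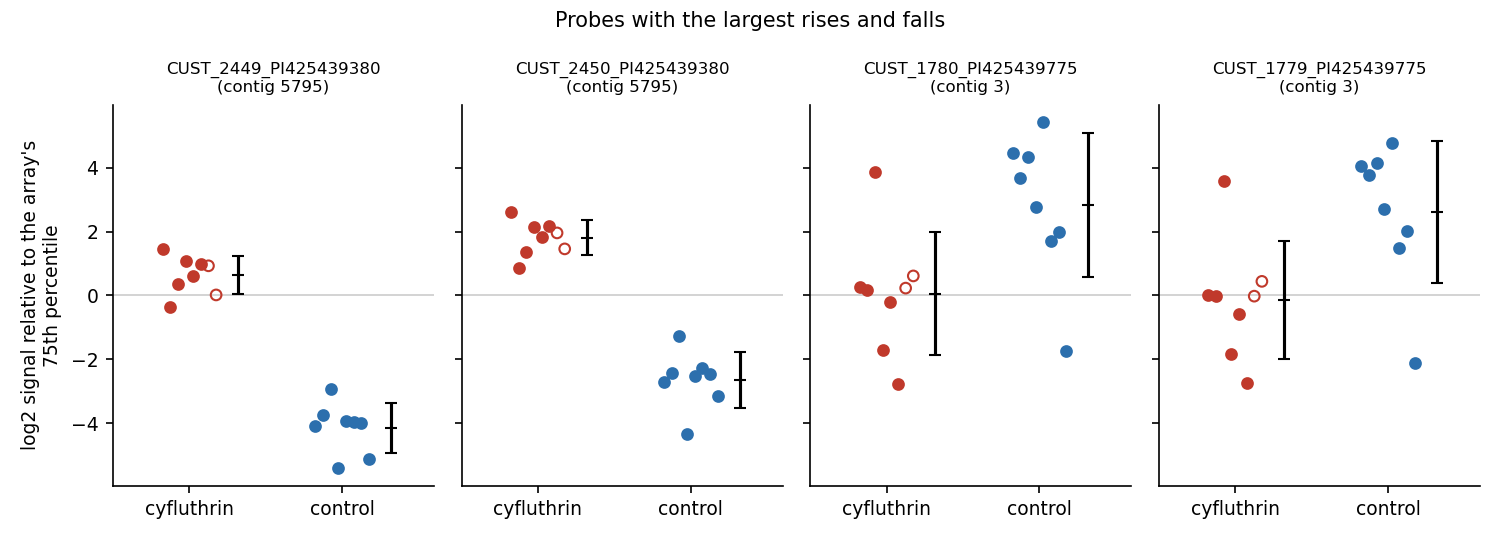
Log2 signal relative to the array's 75th percentile for the probes with the largest rises (contig 5795) and falls (contig 3). Each point is 1 array (red, exposed; blue, control; open points, the 2 dim arrays), and black bars give the mean ± SD over the 8 arrays of a group; the groups do not overlap for contig 5795, while for contig 3 they do.

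Different probes of a contig gave the same picture. They were read from the same extracts on the same arrays, so their agreement bears on the probes and not on the cause of a difference. Of 3810 contigs with a pair of tested probes, 738 had both past the threshold, 409 of them higher and 329 lower. In none of the 738 did the probes go opposite ways, against 1 of 1282 without the 2 dim arrays. With all arrays, a further 434 had 1 probe past the threshold, and in 407 of these the other probe had the same sign. Across contigs, which are not independent replicates, the log2 fold changes of the probes correlated with Pearson's r = 0.933 and Spearman's rho = 0.918, and their median absolute difference was 0.092. The array's probes came in 3 design sets, and 25.7%, 24.3% and 25.8% of their tested probes passed the threshold.

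**Figure D4:**
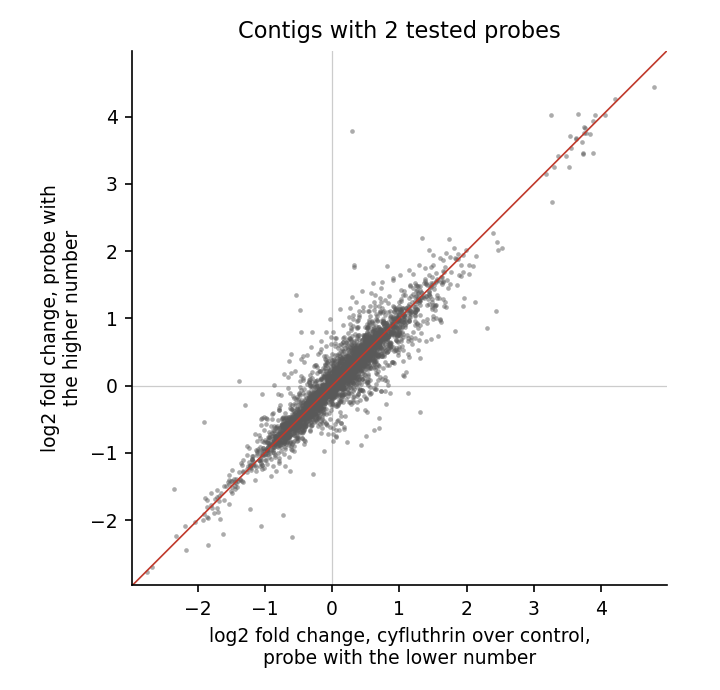
Log2 fold change, cyfluthrin over control, of the probe with the lower number (horizontal) and with the higher number (vertical) for the 3810 contigs with a pair of tested probes; the red line marks equal values. Points follow the line (r = 0.933), and the contigs with rises above 8-fold lie apart from the rest.

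Every slide held 4 arrays of 1 group, and exposed and control arrays were scanned on different days, so scan day and exposure cannot be told apart. Slides within a group could be compared. No probe passed the threshold between the slides of the exposed group (limma, 417 probes at an unadjusted p under 0.05) or between those of the control group (478 probes). After normexp background correction the exposed slides again gave 0 calls but 4898 probes at an unadjusted p under 0.05, which fell to 329 without the 2 dim arrays. Of the 4 pairings of an exposed with a control slide, each of 4 arrays against 4, the first exposed slide gave 1147 calls against slide 3 and 1913 against slide 4. The second exposed slide, which carries the 2 dim arrays, gave 74 and 68.

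Agreement between replicate arrays is an outcome of this study in its own right. The mean correlation across probes between arrays was 0.882 within the exposed group (28 pairs, 0.721 to 0.970) and 0.947 within the controls (28 pairs, 0.907 to 0.980). Without the 2 dim arrays it was 0.939 within the exposed group. The correlation between groups was 0.882, or 0.913 without the 2 dim arrays. The median SD of a probe over arrays was 0.62 in the exposed group, 0.34 without the 2 dim arrays and 0.29 in the controls, on the log2 scale. The median SD of repeated spots within an array was 0.106 ± 0.041 (SD, n = 8) in exposed and 0.091 ± 0.023 (SD, n = 8) in control arrays, a difference within the spread between arrays (two-sided exact permutation test, p = 0.395, adjusted p = 0.527).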

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

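Of the tests in this part, the slide comparisons within groups and the splits of the arrays were chosen before their results were seen. Setting the slides of a group against the slide pairings between groups, and the count of scan days, were chosen after. Of the per-array measures and named probes examined in groups of 8 arrays, 1 value was flagged by its gap to the nearest value. Cyfluthrin 8 had a mean correlation of 0.767 with the arrays of its group, where the next lowest exposed array, cyfluthrin 7, had 0.869. The gap was 0.709 of the group's range, where the limit was 0.526. This rule can miss 2 extreme arrays, since each shortens the gap of the other. For cyfluthrin 8 the gap was only 0.295 for the log2 75th percentile and 0.409 for the spike-ins. The nearest array was cyfluthrin 7, which was also dim, so a lack of flags there does not mean that these arrays were ordinary. Chance flags about 1 in 20 groups, and 18 were examined.

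Its signal was low throughout. Relative to the other 14 arrays, the median log2 signal of the 1000 brightest tested probes was -6.22 on cyfluthrin 8 and -3.18 on cyfluthrin 7. The spike-in controls stood at -4.50 and -2.44 on the same scale. The probes less the spike-ins gave -1.72 and -0.74, where this difference had an SD of 0.34 over the other 14 arrays. Cyfluthrin 1, one of those 14, stood at -0.89, so that cyfluthrin 7 lay within their range.

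Among 100 splits of the 16 arrays into 8 and 8, the real one included, 1 gave as many calls as the real 2493. The highest other split gave 14, so random mixes of the arrays did not give as many calls. These splits mix slides and scan days, so they cannot exclude differences between slides or days that arose by chance. Without the 2 dim arrays 1 of 100 splits gave as many as the real 3892, and the highest other gave 301. The control slides gave 0 calls and at most 561 probes at an unadjusted p under 0.05 over the settings run, against 68 calls and 2129 such probes in the slide pairing between groups with the fewest calls, which argues against differences between control slides of that size as the source. The exposed slides also gave 0 calls, but up to 4898 probes at an unadjusted p under 0.05 (normexp, with the 2 dim arrays). That count was 417 with the settings of the report, and 329 under normexp without the 2 dim arrays, which leaves 4 arrays against 2. Both dim arrays lie on slide 2, so the 4898 need not reflect a difference between slides as such. A part of the differences between exposed slides stays open. Scan day or another step shared by all arrays of a group cannot be told apart from exposure, because 0 scan days hold both groups.

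For the comparisons of slides within a group the real count was 0, which all 35 splits of the 8 arrays into 4 and 4 reach whatever the data, so these splits decide nothing. The highest other split gave 0 calls in the exposed group and 2 in the control group.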

How the results depend on the processing

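All alternatives without cyfluthrin 7 and 8 and the fit with 1 probe per contig were chosen after seeing the data. Both the number of calls and the probes called changed with the settings, and the cause was not tested except where fewer arrays or probes entered. Of the 2493 reported probes, median scaling called 1891, quantile normalization 1186, spike-in scaling 1161, the authors' deposited values 1119, normexp 849, the filter on all 16 arrays 346 and slide means 169. Against 2493 calls (1584 higher, 909 lower), quantile normalization gave 1445 (548 higher), normexp 1111 (652 and 459) and the authors' deposited values 1324 (486 higher). Median scaling gave 2271 calls with 1002 higher, and spike-in scaling 2468 with 252 higher and 2216 lower. With probes well above background on all 16 arrays 347 of 1875 tested probes passed (116 and 231). Slide means, 2 against 2, gave 174 (129 and 45). Array weights gave 4593 (2862 and 1731), an adjusted p under 0.01 gave 873 (519 and 354), and a 2-fold minimum 1056 (854 and 202). Without slide 1 600 probes were lower, without slide 3 377 passed (199 and 178) and without slide 4 223 (146 and 77). Leaving out 1 array gave 1899 (without control 3) to 3542 calls (without cyfluthrin 8), 1191 to 2287 of them higher and 708 to 1255 lower. Without the 2 dim arrays 3892 passed (2512 and 1380), and 3350 with quantile normalization added (1709 higher, 1641 lower). Still without them, slide as a random block gave 5091 (3315 and 1776) and normexp 1542 (909 higher). Leaving out control 1 as well gave 3779 (1498 lower). With 1 probe per contig 1522 of 5955 passed (996 and 526). Slide as a random block gave 2781 calls, with a correlation within slides of -0.025, and of -0.116 without the 2 dim arrays. A negative correlation makes this test less strict, so the higher counts under it add no support.

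Whether the replicate numbers pair the arrays stayed undecided. Deviations of same-numbered arrays correlated from -0.11 to 0.57, with 4 of the 8 over 0.1, and 3 arrays correlated best with their own number. Same-numbered arrays also lay at the same position of their slides. With the replicate number as a block 2250 probes passed (1459 higher, 791 lower).

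The probes of contig 5795 passed under all 38 settings run for them, with log2 fold changes of 2.52 to 4.96 and 2.76 to 4.64. Of the 57 probes that rose at least 8-fold, 51 passed with slide means and 55 without slide 4, and all that were tested passed under the other settings run. The probes of contig 3 kept their direction under all 38 but missed the threshold under 22 (CUST_1780_PI425439775) and 21 (CUST_1779_PI425439775). Slides within a group gave 0 calls under every alternative run. At an unadjusted p under 0.05 the exposed slides gave 417 probes with the settings of the report and 4898 with normexp (329 when the 2 dim arrays were left out, a fit chosen after seeing the data), and the control slides 478 and 383. The mean correlation within the exposed group was 0.729 with normexp, and within the controls 0.910 with probes above background on all arrays. The median SD over arrays was 0.75, 0.69 and 0.48 in the exposed group and 0.26, 0.22 and 0.21 in the controls with quantile normalization, normexp and probes above background on all 16 arrays. Alternatives that need annotation (gene lists, 1 probe per annotation text) were not run. Low signal over background on cyfluthrin 7 and 8 limits what can be said of dim probes.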

Other observations

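Of the tests in this part, that of other scalings was chosen before its result was seen and the rest after. The 57 probes that rose at least 8-fold moved as 1 unit also within the groups. Control 3, with a set median of -2.33 relative to the exposed mean, and control 8, with -4.80, differed by more than 2 log2 units although both were unexposed, and the probes of the set shared such deviations. Over 14 arrays, the 2 dim ones left out, a probe's deviations within groups were correlated with the mean of the rest of the set. The median correlation was 0.880, while 1000 random sets of probes of like signal level had a median of 0.117 and a highest value of 0.359. The random sets were not matched on spread within groups or on pairs of probes of 1 contig, so a part of the gap may stem from these.

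The rise of these probes remained under other scalings and without the 2 dim arrays. Of the 57 probes, 57 passed the threshold, higher, under each of 3 other scalings and without these arrays. The scalings moved the median log2 fold change of all tested probes from 0.16 to -0.49 at most. As the set was picked for a rise of at least 8-fold in these same data, such shifts could hardly undo it. How far the 57 probes rose did depend on the processing, with 32 of them at least 8-fold higher under spike-in scaling and 0 after normexp. Normexp without the 2 dim arrays gave 19. A hypothesis is that the set comes from 1 source of RNA present in all extracts at different amounts, which the correlation of 0.880 is consistent with. Such a source may be a group of genes under common control that answers to the exposure, or another organism living in or on the animals; the files pair no contig with a name that would tell these apart. A step shared by all arrays of a group also stays open, because no slide holds both groups.

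A different kind of variation ran across the treatment. Over the 14 arrays, 159 tested probes on 101 contigs had an SD within groups above 2 on the log2 scale, against a median of 0.32 for all tested probes. By the correlation of their deviations, 111 of them (72 contigs) formed 1 block and 36 (21 contigs) another. The median scaled signal of the first block was -3.39 in cyfluthrin 2, -4.40 in cyfluthrin 5, -4.87 in control 4 and -4.12 in control 5. On the other exposed arrays it was 1.37, 1.08, 0.64, 0.15, -0.48 and 1.16 (cyfluthrin 1, 3, 4, 6, 7 and 8). On the other controls it was 1.03, 1.69, 2.60, 2.74, 1.56 and 1.99 (control 1, 2, 3, 6, 7 and 8). The block spanned 195-fold over the 14 arrays. Of its 111 probes 0 passed the threshold for exposure (4 at an unadjusted p under 0.05) and 1 did without the 2 dim arrays, but the probes were chosen for a wide spread within groups, which leaves little room to pass. The block's median was -0.48 ± 2.20 (SD, n = 8) in exposed and 0.33 ± 3.03 (SD, n = 8) in control extracts (two-sided exact permutation test, p = 0.546).

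Noise of single probes is argued against by a block formed again from 1 probe per contig. Its largest cluster held 44 probes, 43 of them in the first block, and the held-out other probes of the same contigs followed with a median r of 0.997, where random held-out probes reached at most 0.183. Slide and array position are argued against by arrays of 1 slide or 1 position that lay 1.52 or more log2 units apart. A hypothesis is that the block may mark a state of the animals that the labels do not give, such as sex or moult stage. Under it the extracts with low signal would hold few or no animals in that state. The span does not tell whether the other extracts came from 1 animal or several. The labels speak of as many amphipods as extracts but do not state outright that an extract is 1 animal. As 0 of the block's probes have a gene name in the files, the hypothesis was not tested.

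The second block had medians of 2.61, -2.96, 1.77, -3.96, -3.07, -4.33, -2.08 and -1.15 in cyfluthrin 1 to 8 and of 3.03, -0.14, 1.88, -0.71, 2.08, -0.27, -1.32 and -4.99 in control 1 to 8. The groups differed by -1.59 in the mean of these medians, less than the SD within either group, 2.58 and 2.52 (n = 8 each, two-sided exact permutation test, p = 0.226, adjusted p = 0.453 over both blocks). Of its 36 probes 2 passed the threshold for exposure, and these are the probes of contig 3, named above as the largest fall.

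In the first of the 3 design sets, contigs next to one another in the order of probe numbers had related fold changes. Pearson's r was 0.115 over 1891 neighbouring pairs, above the highest value of 10000 shuffled orders, 0.094 (permutation p = 0.0001, the smallest they can give, adjusted p = 0.0003). It was 0.114 without the contigs of the 57 probes and 0.163 without the 2 dim arrays. Neighbours in this set also had related signal levels (r = 0.111), and r of the fold changes was 0.162 after the trend with level was removed. Their deviations within groups, which exposure does not enter, correlated with a median r of 0.181, against 0.097 for random pairs. Neighbours may thus be related apart from the exposure, but this gap was not tested. In the other sets the r of fold changes was -0.015 and 0.003 (adjusted permutation p = 0.9 for both). Spots printed side by side had r = 0.0065.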
